A study of Mus musculus with 4 samples.

How the data were processed

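The series holds 4 single-colour (Cy3) Agilent whole-genome mouse arrays of testis RNA at postnatal day 7 from mice with a FLAG-tagged Nanos2 transgene, 2 of FLAG immunoprecipitates and 2 of Input. Groups and replicate numbers were taken from the sample titles. The series' design text says that the duplicates are biological, and the labels name no animals. A description field of every sample names a fetal gonad, whereas titles and characteristics give day 7, which is used here. The labels' protocols describe total RNA extraction and cRNA labelling and do not describe the immunoprecipitation.

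Per the file headers, the arrays were scanned and their spot intensities extracted with Agilent Feature Extraction, given as version 9.5 in the submitters' processing notes. The deposited intensity files hold, per the file headers, a processed signal that is background-subtracted, together with raw median signals and local background intensities and flags for spots that are well above background, saturated or outliers. The deposited table of the series holds the authors' values on a log2 scale. Set against the scanner files, each of its columns was log2 of the processed signal less a constant, within 0.01 for 99.6% of probes, which brought the 75th percentile of every array to 9.76, and the column medians were 6.18, 6.25, 6.25 and 6.15 (Input 1, Input 2, FLAG IP 1, FLAG IP 2). Its scale and centring are thus known, and the software of the scaling is not given in the sources used here.

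Each array held 43379 spots other than controls, for 41174 probes. Between 62 and 90 spots per array were left out as outliers, 0 were saturated, and spots of the same probe were averaged. The main values are log2 of the processed signal minus the array's 75th percentile. A probe counted as well above background on an array when at least a share of 0.5 of its spots carried that flag. The files used here hold accessions and no gene names, so a probe was named by matching its accession, without version, to the RefSeq transcripts of assembly GRCm38.p6. This named 22951 probes (55.7%) with 16358 symbols, and 18223 probes kept their accession. The probes were designed on an older build, so no coordinates are given and annotations of position are not used here. For a gene with several probes the brightest over all 4 arrays was used. Of 5072 genes with more than 1 tested probe, 37 (0.73%) had probes called in opposite directions. Of 33377 features, the 21589 well above background on both arrays of at least 1 group were tested, of which 13253 had a symbol. Sohlh1, Zbtb16 and Gapdh had no probe matched to them and are not analysed here.

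FLAG IP and Input were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates, two-sided), with Benjamini-Hochberg adjustment over all tested features and calls at an adjusted p under 0.05. All adjusted p-values of genes come from this model unless another setting is named, and all errors of changes are its moderated standard errors. Features changed by 2-fold or more in all array pairs were also counted without a test. With 2 arrays per group no test of the other splits of the samples was made beyond these counts. A transcript not well above background on either array of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal well above background.

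Before the data were examined, 22 gene lists were fixed: undifferentiated and differentiating spermatogonia, meiotic prophase, general germ cell, piRNA pathway, reported NANOS2 readouts, Sertoli, Leydig, peritubular myoid, endothelial, macrophage and red blood cells, the CCR4-NOT complex, P-body and translational repression, mTOR pathway, cell cycle, respiratory chain, ribosomal proteins, histones, extracellular matrix, zinc finger and chromatin regulators, and immediate early and stress genes. Of their 486 tested genes 14 were in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over the 22 lists. Camera with an estimated correlation, which rests on 2 residual degrees of freedom here, called 0 lists, with 1 at an unadjusted p under 0.05 and a smallest adjusted p of 0.44. Fry, which asks whether a list's genes move on balance one way and does not compare it with other genes, called 9.

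The rule for named genes, also fixed before the data were examined, took the 12 genes higher and the 12 lower with the largest change among those called, well above background on all 4 arrays and with the groups' arrays not overlapping, leaving out clone names. It added up to 4 members of each list with the largest change, called ones first, and genes of interest fixed singly. Some genes that the rule takes are not reported here. List members named beyond these were chosen after their values were seen, as examples: Foxo1, Id4, Pax7, Cdh1, Ret, Utf1, Edc4, Ybx1, Myc, Hspb1 and Pan2.

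The fit was tested on simulated data with the real features, means and fitted spread. With 200 changed features of 21589, it called 64.0% of those changed 4-fold and 0% of those changed 2-fold, of which 88.0% had an unadjusted p under 0.05, and 8.57% of its calls were false. With 8000 changed features it called 84.4% of 2-fold and 97.8% of 4-fold changes, and 3.18% of its calls were false. The simulated features were independent of each other, and their spread was drawn from the distribution that the fit itself assumes. The shares of false calls are thus not error rates of the real calls.

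Alternatives were quantile normalization, median centring, scaling to spike-in control spots, normexp background correction with an offset of 50, the authors' deposited log2 table, other filters on dim probes, the mean of a gene's probes, single probes, the replicate number as a block, trend and robust moderation, no moderation, a floor on dim signals, other fold thresholds and leaving out each array. Where a scaling moved the median of all features by more than 0.1, changes of genes and lists are given relative to that shift. The mean spot signal was not among the columns used here, so normexp ran on the median spot signal. A block for slide or scan was not run because all arrays shared a slide and a scan, and features of the transcripts themselves (length, base content, sequence elements) were not analysed here. Figures were drawn with matplotlib 3.10.9.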

Results

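RNA recovered with FLAG-tagged NANOS2, an RNA-binding protein of male germ cells, was measured in mouse testis at postnatal day 7. The testes came from transgenic mice that express FLAG-tagged Nanos2 with its own 3′ untranslated region under a Nanos2 enhancer. RNA recovered by immunoprecipitation with the FLAG tag (FLAG IP) and RNA of the starting material (Input) were each hybridised to single-colour Agilent whole-genome mouse arrays, with 2 biological replicates per group and 4 arrays in all. All levels are log2 signals relative to the 75th percentile of the same array, all changes are FLAG IP minus Input on that scale, and errors of changes are limma standard errors with n = 2 arrays per group. Between 66.3% and 68.4% of the 41174 probes were well above background on each array, and the 75th percentile signal was 1474 and 1676 in the Input arrays against 1019 and 1267 in the FLAG IP arrays. The number of arrays limits the precision. The median standard error of a change was 0.17. No array of RNA recovered with the same antibody from testis without the tag was analysed here, so a change shows a different share of a transcript in the FLAG IP and not by itself that NANOS2 binds it.

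The comparison of FLAG IP with Input asks which transcripts are carried with NANOS2 in the postnatal testis. The transcripts most increased in the FLAG IP included Fgf9, a secreted growth factor required for testis formation, at 27.2-fold, and Cd274, which encodes an immune checkpoint ligand, at 19.7-fold. Lhx1, a LIM-homeobox factor that marks spermatogonial stem cells responsive to GDNF, was 17.6-fold higher. Neurog3, a helix-loop-helix factor of undifferentiated spermatogonia, was 13.0-fold higher, and Gtf2a1l, a germ-cell form of a general transcription factor subunit, 14.2-fold. The most decreased included Slc4a7, a sodium bicarbonate cotransporter, at 12.7-fold lower, Rmrp, the RNA component of the ribonuclease MRP, at 11.4-fold lower, and Rps19, a protein of the small ribosomal subunit, at 5.64-fold lower. Of 21589 features tested, 3409 were higher in the FLAG IP and 4606 were lower at an adjusted p under 0.05 in limma, and of these 2005 and 1868 changed by 2-fold or more. Among features with a gene symbol 1204 were higher and 660 lower by 2-fold or more, and among those without one 801 were higher and 1208 lower.

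Fgf9 (RefSeq transcript NM_013518) rose by 4.77 ± 0.26 (SE, adjusted p = 0.0038), from −4.08 ± 0.20 in the Input to 0.69 ± 0.43 in the FLAG IP (SD, n = 2 each). Cd274 (NM_021893) rose by 4.30 ± 0.35 (adjusted p = 0.0046), Lhx1 (NM_008498) by 4.14 ± 0.34 (adjusted p = 0.0047) and Neurog3 (NM_009719) by 3.70 ± 0.28 (adjusted p = 0.0043). The other increased transcripts named by the rule fixed in advance were Cphx1, a homeobox gene, at 3.86, Gtf2a1l at 3.83, Lcorl at 3.78, Nefl, the light neurofilament chain, at 3.65, Samd7 at 3.61, Nr5a2, an orphan nuclear receptor, at 3.59, Grm3, a metabotropic glutamate receptor, at 3.56, and Lrrc3b at 3.53. The 12 had adjusted p between 0.0038 and 0.0057. Lcorl rested on its brightest probe, and the changes of its other probes were 0.33 and 0.22, with adjusted p = 0.22 and 0.41.

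Among the decreased transcripts, Slc4a7 (NM_001033270) fell by 3.66 ± 0.58 (SE, adjusted p = 0.013), Rmrp (NR_001460) by 3.51 ± 0.36 (adjusted p = 0.0064) and Rps19 (NM_023133) by 2.49 ± 0.15 (adjusted p = 0.0039). Cdkn2a fell by 2.29 ± 0.15 (adjusted p = 0.0040). The remaining changes were −2.45 for Chtf8, −2.32 for Mdfi, −2.22 for Thbs1, the matrix protein thrombospondin, −2.13 for Pdgfd, a platelet-derived growth factor, −2.11 for Mageh1, −2.03 for the matrix proteins Dpt and Tnxb, and −2.01 for Aph1a, a subunit of gamma-secretase. The other probe of Tnxb had a change of −0.78 (adjusted p = 0.024). Averaging the probes of a gene ended the call of Thbs1 (−0.67, adjusted p = 0.069), and without a filter on dim probes Dpt (adjusted p = 0.058) and Tnxb (adjusted p = 0.053) were not called.

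**Figure D1:**
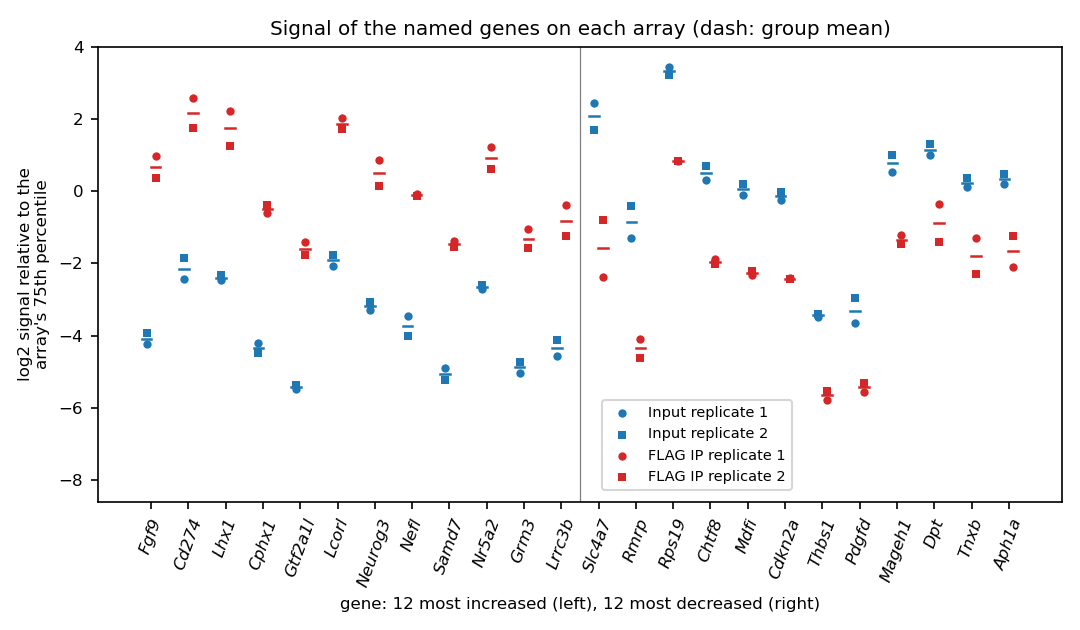
Signal on each of the 4 arrays of the 12 transcripts most increased (left) and the 12 most decreased (right) in the FLAG IP, as log2 signal relative to the array's 75th percentile. Points are single arrays, with circles for replicate 1 and squares for replicate 2, blue for Input and red for FLAG IP, and dashes are group means of n = 2. The rule that chose these 24 transcripts required that red and blue points not overlap. Slc4a7 has the widest spread between its FLAG IP arrays (SD 1.11).

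The replicates of a group resembled each other more than the groups did. Across the tested features, the Pearson correlation was 0.994 between the Input arrays, 0.989 between the FLAG IP arrays and 0.952 to 0.958 between a FLAG IP and an Input array, where features are not independent replicates. The SD of the difference over features was 0.33 between the Input arrays, 0.47 between the FLAG IP arrays and 0.88 between the group means. Counted without a test, 1462 features were at least 2-fold higher and 1140 at least 2-fold lower in all FLAG IP by Input array pairs. The splits that put a FLAG IP and an Input array on each side gave 3 and 20 such features in total, against 2602 for the real groups. In those splits a difference between FLAG IP and Input enters the array pairs with opposite signs. Low counts were thus built in, and they give no baseline for the 2602. Between single replicates, 1.61% of features differed by more than 2-fold for Input and 4.49% for FLAG IP.

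Of all calls 42.5% were higher in the FLAG IP, but 4.08% when arrays were scaled to spike-in control spots, which gave 590 higher and 13873 lower and moved the median of all features by −0.98. Relative to that shift 1979 were higher and 1901 lower. Without Input replicate 1 the calls were 997 higher and 735 lower, without Input replicate 2 they were 1047 and 595, and 39 and 40 of the 98 named transcripts that were called stayed called.

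Transcripts of undifferentiated spermatogonia, the stem and progenitor cells of the male germ line, rose as a group. Of 24 tested members 15 were higher, 1 was lower and 8 were not called, with the same 15 and 1 adjusted over the list alone. The list median was 1.21, a 2.32-fold increase, and 1.15 with members not measured above background set at their bound. Besides Lhx1 and Neurog3, Eomes, a T-box factor, rose by 4.09 ± 0.29 (adjusted p = 0.0040), with its Input level well above background on 1 of 2 arrays. Bcl6b, a transcriptional repressor induced by GDNF, rose by 2.39 ± 0.13 (adjusted p = 0.0038). Foxo1 (2.35), Id4 (1.86), Pax7 (1.79) and Cdh1 (1.73) were also called higher, and Ret, the signalling receptor for GDNF, was at least 2.30-fold higher, since it was not well above background in the Input. Utf1, a chromatin-associated factor of these cells, fell by 0.65. The list stood above the other features in limma's camera with the preset correlation (adjusted p = 9.0e-06), and had adjusted p = 0.44 with an estimated correlation. Under normexp background correction its median was 0.78 (adjusted p = 7.8e-06).

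Transcripts encoding components of P-bodies and translational repression, the cytoplasmic machinery that silences and decaps mRNA, also rose as a group, by a median of 0.57. Of 24 members 8 were higher, 2 lower and 14 not called, and 10 were higher and 3 lower when adjusted over the list alone. Patl1, a decapping activator, rose by 1.09 ± 0.17, Lsm14a by 0.85 ± 0.15 and Xrn1, the cytoplasmic 5′ to 3′ exonuclease, by 0.85 ± 0.18. Edc4, a scaffold of decapping, and Ybx1, a cold-shock RNA-binding protein, were lower, at −0.67 and −0.70. The list was called in camera (adjusted p = 0.0024), had adjusted p = 0.44 with an estimated correlation, and had a median of 0.39 under normexp background correction.

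Ribosomal protein transcripts fell, by a median of 0.74 on the log2 scale, with 59 of 84 members lower and the other 25 not called, and 67 lower when adjusted over the list alone. After Rps19, the members with the largest changes were Rps15 (−1.77 ± 0.19), Rpl4 (−1.76 ± 0.17) and Rps6 (−1.76 ± 0.37), of which Rps6 lost its call under quantile normalization (adjusted p = 0.055). Mitochondrial respiratory chain transcripts had a median of −0.68, with 24 of 49 lower, 25 not called and 33 lower when adjusted over the list alone. Ndufa3 fell by 1.29 ± 0.17, Ndufb9 by 1.19 ± 0.15, Cox6b1 by 1.18 ± 0.19 and Ndufs4 by 1.15 ± 0.15. Replication-dependent histone transcripts, which end in a stem-loop and carry no poly(A) tail, had a median of −0.62, with 12 of 28 lower and 13 when adjusted over the list alone, among them H2bc12 (−1.32 ± 0.25), H2bc14 (−1.28 ± 0.25), H2aw (−1.27 ± 0.23) and H3c1 (−1.22 ± 0.25). The adjusted p in camera was 1.5e-11 for ribosomal proteins, 1.7e-06 for the respiratory chain and 0.0055 for histones, and in the same order adjusted p = 0.66, 0.62 and 0.71 with an estimated correlation. Quantile normalization reduced the medians to −0.39 for ribosomal proteins (adjusted p = 9.0e-05) and −0.43 for the respiratory chain (adjusted p = 6.3e-04). Fry ended the call of the histones (adjusted p = 0.13).

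Of the lists for somatic cells and their products, 5 were lower in the FLAG IP on the same arrays, and the endothelial and red blood cell lists were not called (adjusted p = 0.12 and 0.18). Extracellular matrix and secreted protein transcripts had the lowest median of all lists, at −1.03, with 15 of 28 lower and 16 when adjusted over the list alone. Col3a1, a fibrillar collagen, fell by 1.64 ± 0.29, Fbn1, fibrillin, by 1.62 ± 0.30, Lama2 by 1.58 ± 0.34 and Fn1, fibronectin, by 1.49 ± 0.38, and the calls of Col3a1 and Fn1 ended when probes were averaged (adjusted p = 0.091 and 0.096). Of the Sertoli cell markers 12 of 28 were lower, 15 when adjusted over the list alone, with a median of −0.55. Tsx was at least 2.81-fold lower, since it was not well above background in the FLAG IP, Ptgds, prostaglandin D synthase, fell by 1.32 ± 0.14, Defb36 by 1.13 ± 0.17 and Vnn1 by 1.03 ± 0.15. Of the macrophage markers 7 of 12 were lower, 9 when adjusted over the list alone, with a median of −0.61. The receptor adaptor Tyrobp fell by 1.89 ± 0.18, Aif1 by 1.38 ± 0.24, Fcer1g by 0.87 ± 0.14 and Mrc1 by 0.85 ± 0.20. The adjusted p in camera was 1.8e-04 for the matrix, 2.6e-04 for Sertoli cells and 0.0054 for macrophages, and in the same order adjusted p = 0.71, 0.44 and 0.44 with an estimated correlation. Fry ended the call of the matrix list (adjusted p = 0.14).

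Leydig cell transcripts had a median of −0.72, or −0.67 with members not measured above background set at their bound, and 7 of 14 were lower, the same number as when adjusted over the list alone. Insl3, the insulin-like hormone of Leydig cells, fell by 1.81 ± 0.34, Hao2 by 1.18 ± 0.25 and Hsd3b6, a steroidogenic enzyme, by 1.18 ± 0.20, while Lhcgr, the receptor for luteinizing hormone, was at least 1.76-fold lower. Peritubular myoid transcripts, of the contractile cells around the tubules, had a median of −0.61, with 5 of 12 lower and 6 when adjusted over the list alone, including Mylk (−1.24 ± 0.15), Dpysl3 (−0.86 ± 0.19), Actg2 (−0.82 ± 0.15) and Tagln (−0.80 ± 0.18). Camera gave adjusted p = 0.026 for Leydig cells and 0.028 for myoid cells, and adjusted p = 0.71 and 0.51 with an estimated correlation. Leaving out Input replicate 1 (adjusted p = 0.092) or testing with fry (adjusted p = 0.17) ended the Leydig call, whose median was −1.11 without Input replicate 2, and leaving out FLAG IP replicate 2 (adjusted p = 0.058) or scaling to spike-in spots (adjusted p = 0.13) ended the myoid call.

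**Figure D2:**
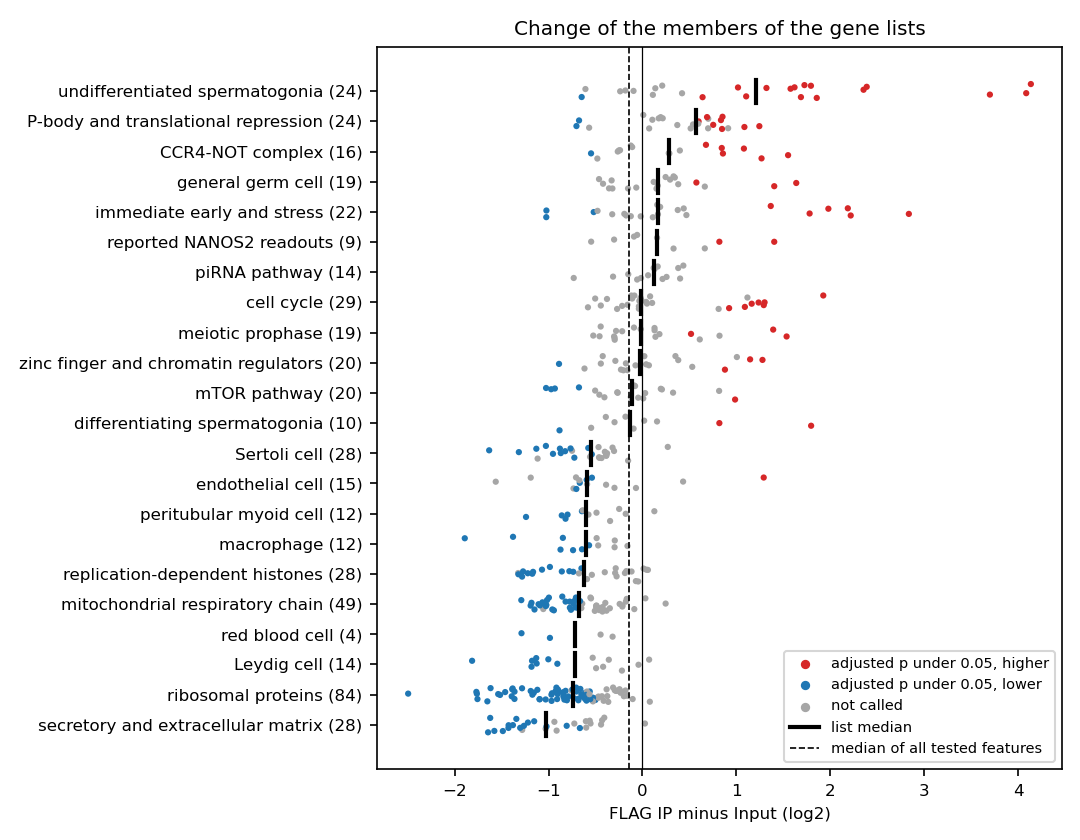
Change in the FLAG IP of each tested member of the 22 gene lists, ordered by list median, with the number of tested members in parentheses. The horizontal axis is FLAG IP minus Input in log2 units, points are genes (red, higher and blue, lower at an adjusted p under 0.05 in limma, grey, not called), thick bars are list medians, and the dashed line is the median of all tested features, −0.15. Undifferentiated spermatogonia have the highest median, 1.21, and extracellular matrix the lowest, −1.03.

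The remaining 12 lists were not called in camera, and their counts of members called were the same when adjusted over the list alone unless stated. Immediate early and stress genes had 6 of 22 members higher, 3 lower and a median of 0.16 (adjusted p = 0.059). Egr2, a zinc finger factor, rose by 2.84 ± 0.14 (adjusted p = 0.0038), Ier3 by 2.22 ± 0.14, Zfp36, which promotes decay of AU-rich mRNAs, by 2.19 ± 0.22 and Egr1 by 1.98 ± 0.15, whereas Myc and the small heat shock protein Hspb1 were lower, each at −1.02. This list passed at an adjusted p of 0.022 under spike-in scaling, 0.027 under quantile normalization, 0.049 with the replicate block, 0.046 with trend and robust moderation and 0.019 in fry, and its median was −0.01 under normexp background correction. The CCR4-NOT list holds Cnot genes of the deadenylase that NANOS2 is known to recruit, together with Btg1, Btg2, Tob1, Tob2, Pan2 and Pan3. Of its 16 tested members 6 were higher, among them Btg1, Tob1 and Pan3, and 1 was lower, Pan2. These counts are therefore not those of the deadenylase alone, and Cnot1 was not among the tested members. The list median was 0.28 (camera, adjusted p = 0.085), −0.04 under normexp background correction and 0.14 without FLAG IP replicate 1. Fry called the list higher (adjusted p = 0.019). Btg1 rose by 1.55 ± 0.15, Cnot6l, a catalytic subunit, by 1.27 ± 0.16, Tob1 by 1.08 ± 0.14 and Cnot4 by 0.86 ± 0.16, and Pan2 was lower at −0.55. Of the cell cycle genes 7 of 29 were higher, among them Ccne1 (1.93 ± 0.18), Cdc6 (1.30 ± 0.17), Rrm2 (1.29 ± 0.16) and Plk1 (1.24 ± 0.15). The median of that list was −0.02 while its mean was 0.28 and the direction in camera was up (adjusted p = 0.085), and the list passed under quantile normalization (adjusted p = 0.014). The other probe of Cdc6 had a change of 0.02. Without FLAG IP replicate 1 the immediate early and cell cycle lists had adjusted p = 0.026 and 0.0040, and without Input replicate 1 they had 0.028 and 0.018. Without FLAG IP replicate 2 they had 0.16 and 0.60, with medians of 0.10 and −0.15, and without Input replicate 2 they had 0.083 and 0.24.

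Germ cell transcripts as a class, and those of later stages, were not called in camera. General germ cell markers had 3 of 19 members higher, 2 when adjusted over the list alone, and a median of 0.16 (adjusted p = 0.13), with Tex13b at 1.64 ± 0.13 and Taf7l, an X-linked paralogue of a TFIID subunit, at 1.40 ± 0.16. This list passed under quantile normalization (adjusted p = 0.027). Meiotic prophase genes had 3 of 19 higher, 2 when adjusted over the list alone, and a median of −0.02 but a mean of 0.13 (adjusted p = 0.46). Sycp1, a transverse filament protein of the synaptonemal complex, rose by 1.54 ± 0.21, Mei4 by 1.39 ± 0.15 and Msh4 by 0.52 ± 0.14. Differentiating spermatogonia had 2 of 10 higher and 1 lower, a median of −0.14 and a mean of 0.04 (adjusted p = 0.89). In that list Lin28b rose by 1.80 ± 0.19, although its other probe had 0.28, and Crabp1 fell by 0.88 ± 0.18. None of the 14 piRNA pathway genes was called by limma, 1 had an unadjusted p under 0.05, and the list median was 0.12 (adjusted p = 0.34), with Piwil2 at −0.73 ± 0.26 and Asz1 at 0.44 ± 0.27. The medians of the germ cell and piRNA lists were −0.01 and −0.04 under normexp background correction. Without FLAG IP replicate 1 the germ cell and meiotic prophase lists passed, with medians of 0.37 and 0.27 (adjusted p = 0.0089 and 0.026), and without FLAG IP replicate 2 their medians were −0.06 and −0.47 (adjusted p = 0.80 and 0.60).

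In the mTOR pathway list 1 of 20 members was higher and 4 were lower, 3 when adjusted over the list alone, with a median of −0.11 (adjusted p = 0.47). Rheb, the GTPase that activates mTOR, rose by 0.99 ± 0.14 while Mtor itself fell by 0.97 ± 0.13. Zinc finger and chromatin regulators had 3 of 20 higher and 1 lower, a median of −0.03 and a mean of 0.11 (adjusted p = 0.46), with Suz12, a Polycomb subunit, at 1.28 ± 0.14, Kdm6a at 1.15 ± 0.24 and Zfx at 0.88 ± 0.14. Endothelial markers had 1 of 15 higher and 4 lower, 3 when adjusted over the list alone, and a median of −0.59 (adjusted p = 0.12). Flt1, a receptor for vascular endothelial growth factor, rose by 1.29 ± 0.30, with 0.86 (adjusted p = 0.087) for its other probe, and Ramp2 (−0.70 ± 0.14) and Robo4 (−0.67 ± 0.15) fell. Of 4 red blood cell genes 2 were lower, with a median of −0.72 (adjusted p = 0.18), Hba-a1 at −1.29 ± 0.27 and Hbb-bt at −0.99 ± 0.26. Another probe of Hbb-bt was called higher, at 0.69. Without Input replicate 1 the endothelial list passed (adjusted p = 0.024, the same without FLAG IP replicate 1, and 0.028 without a filter on dim probes), while it had adjusted p = 0.47 without Input replicate 2 and 0.54 without FLAG IP replicate 2. The median of the red blood cell list was −1.01 without Input replicate 2 and −0.42 without Input replicate 1.

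Genes fixed in advance for their part in NANOS2 biology were examined singly. Whether the Nanos2 probe reads the endogenous transcript, that of the transgene or both was not measured. Nanos2 (NM_194064) rose by 1.58 ± 0.22 (adjusted p = 0.010), 2.98-fold, from −3.77 ± 0.15 in the Input to −2.19 ± 0.35 in the FLAG IP (SD, n = 2 each), and Gfra1 (NM_010279), the GDNF co-receptor of stem cells, rose by 1.32 ± 0.18 (adjusted p = 0.0097), with 1.02 (adjusted p = 0.13) for its other probe. Taf7l rose by 1.40 ± 0.16 (adjusted p = 0.0074), and Sohlh2, a helix-loop-helix factor of differentiation, by 0.82 ± 0.18 (adjusted p = 0.026). Dazl, an RNA-binding protein required for germ cell development, had 0.66 ± 0.23 and Kit, the receptor of differentiating spermatogonia, −0.55 ± 0.19, each with adjusted p = 0.077, and the other probe of Dazl had 0.05 (adjusted p = 0.83). Dmrt1 had 0.33 ± 0.14 (adjusted p = 0.12) and Dnd1, a partner of NANOS2, −0.36 ± 0.14 (adjusted p = 0.11). Stra8, which is required for meiotic entry, had 0.16 ± 0.22 (adjusted p = 0.60), Sycp3 −0.09 ± 0.33 (adjusted p = 0.84), Ddx4 0.16 ± 0.25 (adjusted p = 0.64) and Nanos3 −0.18 ± 0.19 (adjusted p = 0.48). The reference transcripts Actb and Hprt had 0.45 ± 0.29 (adjusted p = 0.26) and −0.33 ± 0.20 (adjusted p = 0.24). The list of 9 tested genes reported as NANOS2 readouts had 2 higher, also when adjusted over the list alone, and a median of 0.16 (adjusted p = 0.20), which passed without FLAG IP replicate 1 (adjusted p = 0.045) and was −0.01 under normexp background correction. It was drawn from knowledge of earlier work that may include these samples, so its direction is not independent evidence.

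Without Input replicate 1 the adjusted p was 0.062 for Nanos2, 0.066 for Gfra1 and 0.052 for Taf7l, and without Input replicate 2 it was 0.051 for Taf7l. The call of Sohlh2 ended under spike-in scaling (adjusted p = 0.16), and calls arose for Dazl under quantile normalization (adjusted p = 0.040) and for Kit and Dnd1 under normexp background correction (adjusted p = 0.016 and 0.029).

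**Figure D3:**
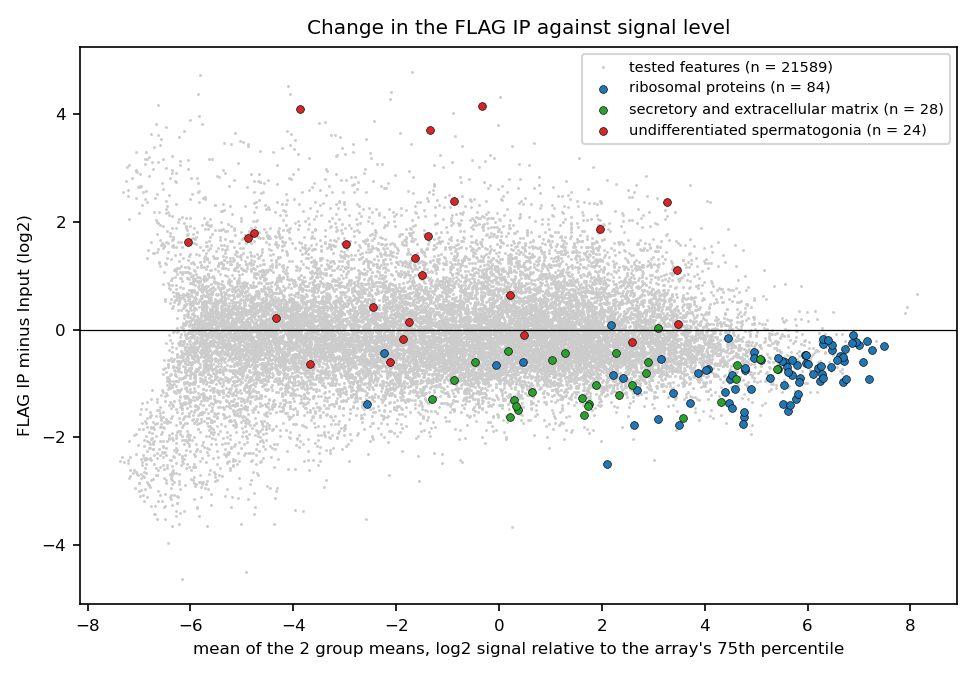
Change in the FLAG IP (FLAG IP minus Input, log2) against signal level (mean of the group means, log2 relative to the array's 75th percentile) for the 21589 tested features, each a grey point. Ribosomal protein genes (blue, n = 84) lie at high signal and mostly below 0, extracellular matrix genes (green, n = 28) mostly below 0 at intermediate to high signal, and undifferentiated spermatogonia genes (red, n = 24) mostly above 0 over a wide range of signal.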

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

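A signal outside the main comparison was seen in the control spots that match Agilent's spike-in RNA, of which the amount added is not given in the sources used here. Averaged over 8 such controls and relative to the array's 75th percentile, their log2 signal was 1.22 and 1.55 on the Input arrays and 2.63 and 2.10 on the FLAG IP arrays, a difference of 0.98, and each of the 8 was higher on both FLAG IP arrays than on both Input arrays. The difference was 1.16 for the 4 dimmer controls and 0.80 for the 4 brighter. With 2 arrays per group no sample could be tested as standing apart from its group.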

How the results depend on the processing

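The crossed pairing, and testing lists against features with a symbol alone, were chosen after seeing the data. No named transcript or list that was called changed direction under any setting once changes were taken relative to the shift of the median, and of all called features 98.7% or more kept their sign, the fewest with single probes. Named transcripts kept their side of the threshold in 1741 cases over the alternatives, lost a call in 310 and gained one in 16, and lists did so in 339, 16 and 19. Under quantile normalization, median centring, the authors' table, single probes, averaged probes, trend and robust moderation and a floor, each count of calls stayed within 1.5 times the values in the report. All 12 most increased transcripts kept their calls under every setting except no moderation, which ended all of them. Of the 12 most decreased 8 stayed called without Input replicate 1, 9 without Input replicate 2, 10 without a filter and 11 with averaged probes. Scaling to spike-in spots gave 590 higher and 13873 lower calls, 479 and 12312 at 2-fold, and 282 and 6495 in all array pairs. By construction this scaling carries the higher spike-in signal of the FLAG IP arrays into every feature. With normexp, lower features numbered 843 at 2-fold and 371 in all pairs, and the cause was not tested. These counts do not allow for its shift of the median of all features, 0.15. All its calls numbered 4145 higher and 4275 lower, or 3087 and 6129 relative to that shift. Without a filter on dim probes 3021 were lower, with 33377 features tested, and requiring signal on all 4 arrays left 700 lower in all pairs, since transcripts dim in the FLAG IP are then excluded. Thresholds of 1.5-fold and 4-fold gave 2730 higher and 3118 lower, and 299 and 174, in all pairs.

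Without moderation of the variance limma called 0 higher and 0 lower, also 0 and 0 at 2-fold, with 7728 at an unadjusted p under 0.05, because 2 residual degrees of freedom remained. Leaving out an array gave 997 to 3717 higher calls and 595 to 4572 lower, 997 to 2284 and 595 to 2184 at 2-fold, 1648 to 2065 higher and 1544 to 1798 lower in all pairs, and 9 to 16 called lists. The lone array of a group was then assumed to vary like the other group. Fewer array pairs also remained, so the counts in all pairs could only stay or rise, whatever array was left out. The low counts of calls came without an Input array (997 and 735 without replicate 1, 1047 and 595 without replicate 2), the 16 lists without FLAG IP replicate 1. Camera with an estimated correlation called 0 of 22 lists, 1 at an unadjusted p under 0.05, and fry 9. Replicate numbers as a block gave 2269 higher and 2290 lower calls. Deviations from the group means of arrays with equal numbers correlated at −0.38 over features, and nothing in the labels pairs the numbers. The crossed pairing called 4321 higher and 6502 lower. A block for slide or scan, and a test of transcript features, were not run. Dim signal limits the fold of transcripts that are not well above background in a group.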

Other observations

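The grouping of genes by symbol and the genes named singly in the next paragraph were chosen after the results were seen. So were the comparison of list members with Nanos2 and the test of dilution by rising transcripts. Also chosen then were matched lists under quantile normalization, median centring and normexp, the other weights and bins of signal and the split by accession. Of 254 tested genes whose symbol starts with Zfp and a number, 92 were higher, 13 lower and the others not called, with a median of 0.40 (limma's camera, adjusted p = 2.3e-07 over the 57 symbol families with at least 20 tested members, and adjusted p = 0.84 with an estimated correlation). Among those with the largest changes were Zfp143 (3.18 ± 0.16), Zfp941 (3.01 ± 0.28) and Zfp248 (2.79 ± 0.14; SE, n = 2 arrays per group), and Zfp385c was at least 3.67-fold higher, since it was not well above background in the Input. The list of zinc finger and chromatin regulators fixed in advance was not called in camera (median −0.03, adjusted p = 0.46). It holds mostly chromatin regulators, so it is no test of the Zfp genes. The Zbtb family, of zinc finger factors with a BTB domain, had 15 of 33 higher and 4 lower and a median of 0.26 (adjusted p = 0.0017, and adjusted p = 0.84 with an estimated correlation), from Zbtb1 at 2.73 ± 0.15 to Zbtb20 at −1.70 ± 0.26. Both families passed under each of 10 other settings of scaling, background, filter, probe rule and left-out array, with medians of 0.25 to 0.45 and 0.14 to 0.37. Mitochondrial ribosomal proteins were lower, with 24 of 47 Mrpl genes lower and 1 higher (median −0.56, adjusted p = 2.3e-04) and 14 of 29 Mrps genes lower (median −0.53, adjusted p = 0.011), each at adjusted p = 0.84 with an estimated correlation, and the Mrps call ended under spike-in scaling and without Input replicate 1 (highest adjusted p = 0.12). In all, 3 families were higher and 6 lower. The third higher family, Fbxo (F-box proteins, median 0.35, adjusted p = 0.049, and 0.84 with an estimated correlation), passed under 3 of the 10 settings. The other lower families were Rpl, Rps, Col and Cox, of which Col had 20 of 34 genes lower and a median of −1.01, Rps, which here includes Rps6k kinases, passed under 9 of the 10 settings (quantile normalization, median −0.21 and adjusted p = 0.18), and Cox under 6. Each of these had adjusted p = 0.84 with an estimated correlation, which called 0 of the 57 families in camera.

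Outside the rule for named genes, Nanos1, the paralogue of Nanos2 better known from the nervous system, rose by 2.67 ± 0.14 (adjusted p = 0.0038), and the long non-coding RNA Kcnq1ot1, which silences imprinted neighbours in the nucleus, fell by 2.99 ± 0.31 (adjusted p = 0.0065), with its FLAG IP level well above background on 1 of 2 arrays.

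The higher level of undifferentiated spermatogonia transcripts was set against 3 technical explanations. Inflated ratios of dim probes would leave the list median among those of random lists matched on signal. It lay at percentile 100 of 10000 such lists, whose median was −0.10 with 95% between −0.39 and 0.24. That range comes from drawing genes and does not measure variation between arrays. Named genes of similar signal thus did not rise as a set. However, camera had already called the list higher on the same arrays, so its percentile adds little separate evidence. The list exceeded its matched lists by 1.31 under median centring and by 0.90 under normexp. The size of the rise thus depended on background correction, and some inflation of dim signals is not excluded. Bulk recovery of all RNA of the cells that make FLAG-NANOS2 stays open. Members were set against Nanos2 with a 95% range of the normal distribution, which is narrower than the model's own 95% intervals. Of 23 members 5 exceeded the change of Nanos2 by more than this range (Eomes, Lhx1, Neurog3, Bcl6b and Foxo1), as did 335 of all tested features. However, 11 members lay below Nanos2 by as much, and the median difference was −0.47. With the model's wider intervals these counts could only stay or fall. Nearest the cut were Foxo1 above (difference 0.78 ± 0.29, SE) and Etv5 below (−0.56 ± 0.28). A first criterion, 3 or more members above Nanos2, was met and was replaced by the median of all members after its result was seen, because it rested on the members with the largest changes. How far Nanos2, read by a single probe, and the other members are specific to these cells was not measured. The Nanos2 probe may also read mRNA of the transgene, which limits Nanos2 as a baseline for this comparison. RNA adhering to the antibody or beads cannot be told apart from binding by NANOS2, because 0 arrays of an immunoprecipitate from testis without the tag were analysed here, and selective association of these mRNAs with NANOS2 stays open as a hypothesis.

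The lower level of ribosomal protein and respiratory chain transcripts could come from compression of bright signals on the FLAG IP arrays. Random lists matched on signal had medians of −0.29 (95% between −0.38 and −0.20) and −0.27 (−0.42 to −0.10), against −0.74 and −0.68 observed. Both lists lay at percentile 0 of 10000 lists (0 for ribosomal proteins, 0 for the respiratory chain). On these 4 arrays this argues against compression that depends on signal alone as the whole cause. However, the brightest spike-in controls, at levels of 5.07 to 5.66 and 6.95 to 7.79, differed by 0.46 and 0.65. The next brightest had 1.14 and the dimmest 1.29. Ribosomal proteins lay near the brightest controls (median level 5.61, respiratory chain 3.74), and matching in bins need not equalise the brightest genes. For ribosomal proteins compression thus stays open. The random lists draw unrelated genes, whereas members of each list varied together (estimated correlation 0.49 and 0.26). Their range is therefore too narrow to show that the shift would recur on other arrays. Quantile normalization, which gives all arrays the same distribution of signal, brought the matched lists to 0.04 (−0.04 to 0.14) and −0.03 (−0.19 to 0.14) and the observed medians to −0.39 and −0.43, again at percentile 0, so part of the fall went with signal level and the difference from the matched lists remained. Dilution by the transcripts that rise would lower all others alike. Random lists matched on signal and drawn from genes not called higher had medians of −0.31 (95% between −0.41 and −0.24) and −0.33 (−0.47 to −0.19). Again both lists lay at percentile 0 (0 for ribosomal proteins, 0 for the respiratory chain). A uniform dilution would not by itself place a list below such genes. However, camera had already called both lists lower on the same arrays, and the reference genes were filtered by their change. The comparison thus adds no separate evidence on dilution. No biological explanation was tested, and whether NANOS2 complexes exclude these mRNAs stays open.

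Features without a gene symbol were more often lower in the FLAG IP than named ones (25.1% of 8336 against 19.0% of 13253), and 15.1% against 16.2% were higher. If dimmer probes were the cause, the difference would vanish at matched signal, but it was 9.03 ± 0.60 percentage points over 10 bins of signal weighted by their number of unnamed features, and 7.29 ± 0.62 as a plain mean of the bins (binomial SE). With 100 bins the weighted difference was 8.84 ± 0.61. These errors treat features as independent and do not measure variation between arrays. The difference that remained at matched signal argues against dimmer probes as the whole cause on these arrays. The difference was nonetheless uneven, at 21.5, 14.1 and 10.2 in the 3 dimmest bins, 1.46, −1.11 and −0.41 in bins 5 to 7 and 12.4 in the brightest, and why it varied with signal was not tested. By kind of accession, the share lower was 31.3% of 326 features starting with TC, 28.9% of 3969 with AK, 22.8% of 514 with NAP, 22.2% of 872 with XM, 21.7% of 1038 with BC, 20.3% of 354 with ENSMUST and 19.0% of 13709 with NM. No biological explanation was tested.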
